A study of Mus musculus with 10 samples.

How the data were processed

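RNA-seq libraries of 10 mouse livers were analysed: 5 from floxed wild-type littermates (Flox) and 5 from mice with a hepatocyte-specific knockout of Me1 (HKO), all on a high-fat diet for 16 weeks. Per the labels, RNA was extracted with Trizol, polyadenylated RNA was purified, and strand-marked libraries (second strand with dUTP) were read in pairs of 150 bp. Each liver has its own column of values, and the numbers in the sample titles are not shared between the groups, so livers were treated as separate mice. The labels write the genotype of the HKO mice as Me1 Alb/Alb, read here as the hepatocyte-specific knockout that the series description names. The labels give no sex, age, litter or batch. Livers are numbered 1 to 5 within each group in the order of their title numbers.

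Per the file headers, the deposited table holds estimated counts and FPKM (read fragments scaled by gene length and library size) for 31218 genes in each liver. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, without saying which step each served. How the authors counted reads shared between genes, and whether the counting used strand, is not given in the sources used here. The estimated counts in the deposited table are whole numbers. Within each liver the deposited FPKM values are the counts divided by a gene length: over 7323 genes with at least 500 counts in all livers, the log2 ratio of count to FPKM differed between livers with an SD across genes of at most 0.00135. The genome build is not given in the sources used here. Of the table's genes, 31131 have an identifier in the mouse reference annotation (GENCODE M21, GRCm38), and 28225 of these have the same start and end there. Coordinates are printed as the deposited table gives them. Pathway terms in the table had 2200 gene ontology entries and 6 KEGG entries replaced by a mark of removal, and those entries were not used here.

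The plan written before the data were examined assumed that FPKM alone would be in the table and named limma on log2(FPKM + 0.5) for that case, and edgeR for the case that counts were present. Counts were present, so edgeR 4.0.16 in R 4.3.3 gave the main test: filterByExpr kept 18065 genes, TMM factors scaled the libraries, and the quasi-likelihood test with the robust option compared HKO with Flox. Log2 fold changes are HKO minus Flox, tests are two-sided, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. CPM values are counts scaled to library size with the TMM factors. Single values were compared by exact permutation of the 252 assignments of 10 livers to groups of 5, for which the smallest two-sided p is 0.00794.

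Gene lists for pathways, liver zones, sex-biased genes, handling and other cell types were written before the data were examined. Of these 43 lists, 41 had at least 5 tested genes and were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. The adipocyte list had 3 tested genes and the exocrine pancreas list had 1, and neither was tested. Beside camera stand its p with an estimated correlation, and fry, which asks whether a list's genes move on balance in one direction and does not compare the list with other genes. For each list the number of genes past the threshold is also given as adjusted over the list alone. A score per liver, the mean log2 CPM of a list's genes, was compared by exact permutation with adjustment over the 41 lists; this score was chosen after the data had been seen. Me1 is in no list.

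Genes were named by a rule fixed at the same time: Me1; the 12 genes with the largest log2 fold change in each direction among those past the threshold with at least 4 of 5 HKO livers beyond the Flox mean, leaving out predicted genes and clone names; and up to 4 tested members with the smallest p in each list described. List members past the threshold are named as examples, and not every gene under the rule is reported here. Genes named outside the rule are said to be so where they appear.

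The depth was 52790000 to 60765120 counts per liver, with TMM factors of 0.896 to 0.965 in Flox and 0.998 to 1.16 in HKO, and 17088 of the tested genes had counts in all livers. Over all genes together replicates differed by far more than counting error, with a chi-square per degree of freedom of at least 55.2 in Flox and 55.5 in HKO. Abundant genes weigh most in this value, so it does not show what limited precision in genes with few counts. The pipeline was tested on simulated data for this comparison, with 200 of 18065 genes changed. It recovered 42.0% of genes raised 2-fold and 40.0% of those lowered 2-fold, 80.0% of those raised 4-fold and 84.0% of those lowered 4-fold, and called 0 of 17865 unchanged genes. Of 40 simulated lists without a change, 0 had a camera p under 0.05. The simulated genes were drawn independently of each other, so this cannot show how often camera calls lists of correlated genes by chance. Their counts followed the distribution that edgeR assumes, with dispersions fitted to these livers. They had no transcripts shared by a few livers only and no trends with gene length, so the simulation does not give the rate of false calls in the real data.

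Alternatives fixed in advance were other pseudocounts, filters, scalings, count models, sample weights, a covariate (the first component of the residuals of the genotype fit), other set tests (estimated correlation, ranks, fry) and leaving out each liver in turn, with DESeq2 1.42.0 as the other count model. Added after the data had been seen were a fit of 8 livers without HKO 4 and HKO 5, a fit of 6 livers (Flox 3 to 5 against HKO 1 to 3), limma on log2(FPKM + 0.5), a fit without genes at least 4-fold higher in HKO 4 and HKO 5 than in every other liver, and a fit with trends of counts with transcript length and GC content removed within each liver. Also chosen after the data had been seen were the marker sets for epidermis, skeletal muscle, heart, X inactivation and the Y chromosome, the KEGG terms of the table (10 to 200 tested genes each), and the decision to judge a list's direction across alternatives by its median relative to all genes.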

Results

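Gene expression was measured in livers of 10 mice on a high-fat diet to ask what changes when hepatocytes lack Me1, the cytosolic malic enzyme that makes NADPH from malate. The mice were 5 floxed wild-type littermates (Flox) and 5 hepatocyte-specific knockouts (HKO). Total counts ran from 52790000 to 60765120 per liver.

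Me1 itself (ENSMUSG00000032418, chromosome 9, 86581371 to 86695953, minus strand) was far lower in every HKO liver. Its FPKM was 36.4 ± 6.18 in Flox and 5.58 ± 0.841 in HKO (mean ± SD, n = 5 each; exact permutation p = 0.00794, the smallest this design can give). The Flox livers ranged from 30.2 to 46.7 and the HKO livers from 4.90 to 7.00, so the label of each library matched its Me1 level, and 15.3% of the Flox mean remained. On the count scale Me1 was 7.65-fold lower, with a log2 fold change of -2.93 (SE 0.13, edgeR adjusted p = 8.5e-07).

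**Figure D1:**
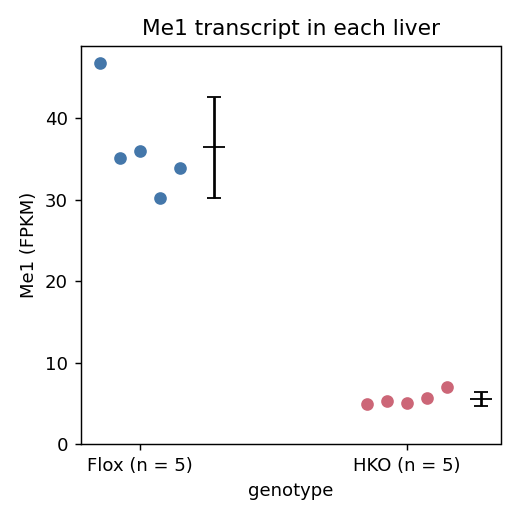
Me1 in each of the 10 livers as FPKM, with the group mean and SD (n = 5 per group). All HKO livers lie at or below 7.00 FPKM and all Flox livers at or above 30.2 FPKM.

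Beyond Me1, HKO livers had lower expression of genes for fatty acid oxidation, amino acid and bile acid metabolism, oxidative phosphorylation and secreted plasma proteins, and higher expression of extracellular matrix, macrophage and NRF2 target genes. These are list calls by camera, none of which passed with an estimated correlation (lowest adjusted p = 0.161). Fry did not call the NRF2 targets (fry adjusted p = 0.0605). In all, 878 genes were higher and 1156 lower in HKO among 18065 tested (edgeR, 43.2% of calls higher). All 5 HKO livers lay above all 5 Flox livers in 797 genes and below them in 1171 genes, together 10.9% of tested genes, where chance gives 0.794%. The first principal component held 29.0% of the variance, with negative scores in all Flox livers and positive scores in all HKO livers. On it HKO 4 and HKO 5 lay furthest out, at 55.8 and 72.0, and HKO 1 to HKO 3 at 13.3 to 21.5. HKO 4 and HKO 5 also carried transcripts of epidermis, of skeletal muscle and of Xist that the other 8 livers had at much lower levels. Without these livers 454 genes were higher and 539 lower, and 382 of the 878 and 512 of the 1156 were called again in the same direction. With trends of counts with gene length and GC content removed, 1110 genes were higher and 753 lower (59.6% higher). In that fit the median log2 fold change of all genes was 0.083, against 0.016 in the main fit, and 15 lists passed camera.

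Of the 41 gene lists tested, camera placed 9 higher and 10 lower in HKO. None of the 19 passed with an estimated correlation (0 lists, lowest adjusted p = 0.161, with 5 lists at an unadjusted p under 0.05), and fry called 8. Other splits of the same 10 livers gave up to 25 lists by camera and up to 2 by fry. In 7 lists the score per liver separated all 5 HKO livers from all 5 Flox livers (exact permutation p = 0.00794 each, adjusted p = 0.0465): fatty acid oxidation, amino acid metabolism, bile acids, oxidative phosphorylation, hepatocyte secreted proteins, extracellular matrix and recruited macrophages.

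Genes of fatty acid oxidation, which includes targets of the nuclear receptor PPARα, were lower. Of 25 genes 17 fell, 0 rose and 8 did not pass (adjusted over the list alone, 18 fell and 1 rose), with a median log2 fold change of -0.40 (camera adjusted p = 7.2e-11, adjusted p = 0.376 with an estimated correlation). Cpt2, which releases fatty acids from carnitine inside mitochondria, fell from 281 ± 9.56 to 181 ± 12.4 CPM (mean ± SD, n = 5 each). Its log2 fold change was -0.63, and those of the β-oxidation enzymes Acaa2, Eci1 and Acadvl were -0.62, -0.46 and -0.40 (edgeR adjusted p = 4.1e-04, 8.0e-04, 0.00302 and 0.00381). All 5 HKO livers lay below all Flox livers in each of these genes. Without HKO 4 and HKO 5 the list had 11 lower genes, and in the 6 livers 3.

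Amino acid, urea cycle and one-carbon metabolism followed the same direction. Of 23 genes 13 fell, 0 rose and 10 did not pass (adjusted over the list alone, 18 fell and 1 rose), with a median of -0.44 (camera adjusted p = 1.5e-09, adjusted p = 0.161 with an estimated correlation). Hpd and Fah of tyrosine breakdown fell by 0.89 and 0.55 on the log2 scale, Cbs by 0.65 and the serine enzyme Shmt2 by 0.51 (edgeR adjusted p = 0.00141, 9.3e-04, 4.7e-04 and 4.6e-04; lower in 5 of 5 HKO livers than in any Flox liver). The list had 9 lower genes without HKO 4 and HKO 5, and 7 in the 6 livers.

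Bile acid synthesis and transport had 9 of 22 genes lower, 0 higher and 13 that did not pass (adjusted over the list alone, 12 lower), with a median of -0.35 (camera adjusted p = 1.9e-07, adjusted p = 0.161 with an estimated correlation). Amacr, Hsd3b7 and Cyp27a1 of bile acid synthesis had log2 fold changes of -0.79, -0.54 and -0.85, and the bile acid uptake transporter Slc10a1 one of -0.57, with all 5 HKO livers below all Flox livers (edgeR adjusted p = 1.5e-04, 4.7e-04, 0.00173 and 0.00382). The list had 7 lower genes without HKO 4 and HKO 5, and 6 in the 6 livers.

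Nuclear genes of oxidative phosphorylation were lower: 6 of 26 fell, 0 rose and 20 did not pass (adjusted over the list alone, 15 fell), with a median of -0.18 (camera adjusted p = 3.1e-08, adjusted p = 0.660 with an estimated correlation). Ndufb10 of complex I fell by 0.42 and Cyc1 of complex III by 0.28 on the log2 scale (edgeR adjusted p = 0.00277 and 0.0195, 5 of 5 HKO livers below every Flox liver). Only 1 of the 26 fell without HKO 4 and HKO 5, as in the 6 livers. Cyc1 lost its call in both (edgeR adjusted p = 0.0950 and 0.136). In the TCA cycle 4 of 22 genes fell, 0 rose and 18 did not pass (adjusted over the list alone, 6 fell), with a median of -0.11 (camera adjusted p = 0.00980, adjusted p = 0.724 with an estimated correlation). That median was 0.05 above all genes after quantile normalization. The call was lost without HKO 4 and HKO 5 (camera adjusted p = 0.215). Sucla2 and Idh3b had log2 fold changes of -0.23 and -0.25 (edgeR adjusted p = 0.0197 and 0.0316, both lower in 5 of 5 HKO livers). Both lost their calls without HKO 4 and HKO 5 (edgeR adjusted p = 0.0996 and 0.155) and in the 6 livers (edgeR adjusted p = 0.209 and 0.147). Gluconeogenesis had 1 of 14 genes lower, 0 higher and 13 that did not pass (adjusted over the list alone, 1 lower), with a median of -0.26 (camera adjusted p = 0.0392, adjusted p = 0.724 with an estimated correlation). The alanine aminotransferase Gpt was that gene, at -0.47 (edgeR adjusted p = 0.00318, 5 of 5 HKO livers below every Flox liver). The list's call was lost without HKO 4 and HKO 5 (camera adjusted p = 0.477).

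Secreted hepatocyte proteins were lower in HKO, except that their median lay 0.02 above all genes after quantile normalization. Of 15 genes 9 fell, 0 rose and 6 did not pass (adjusted over the list alone, 13 fell), with a median of -0.33 (camera adjusted p = 1.1e-10, adjusted p = 0.161 with an estimated correlation). Apoa1, the main protein of high-density lipoprotein, fell 2.19-fold, from 7654 ± 922 to 3494 ± 534 CPM (mean ± SD, n = 5 each; edgeR adjusted p = 4.9e-04). Rbp4, the plasma carrier of retinol, had a log2 fold change of -0.70 (edgeR adjusted p = 5.6e-04). In both genes all 5 HKO livers lay below all Flox livers. Serpina1a and Serpina1d, near-identical copies of α1-antitrypsin whose reads could be split between them, stood at -0.89 and -0.87 (edgeR adjusted p = 8.8e-04 and 6.2e-04, 5 of 5 HKO livers below every Flox liver).

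By liver zone, markers of pericentral hepatocytes fell in 6 of 16 genes, rose in 0 and did not pass in 10 (adjusted over the list alone, 8 fell and 1 rose), with a median of -0.42 (camera adjusted p = 2.5e-04, adjusted p = 0.259 with an estimated correlation). Rgn and Gulo had log2 fold changes of -0.88 and -0.63 and the cytochrome Cyp2e1 one of -0.86 (edgeR adjusted p = 2.9e-04, 0.00102 and 0.00195, 5 of 5 HKO livers below every Flox liver). In the score of the whole list only 2 of 5 HKO livers lay below every Flox liver (exact permutation adjusted p = 0.0813). Flox 1, at 6.76, lay below HKO 4 and HKO 5, at 6.88 and 6.78. Periportal markers did not pass as a list (camera adjusted p = 0.327, median -0.10, 1 of 13 higher, 4 lower and 8 that did not pass; adjusted over the list alone, 4 higher and 5 lower). Among them the urea cycle enzyme Ass1 fell by 0.65 and Pigr by 0.69 on the log2 scale (edgeR adjusted p = 0.00195 and 0.00277, 5 of 5 HKO livers below every Flox liver).

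**Figure D2:**
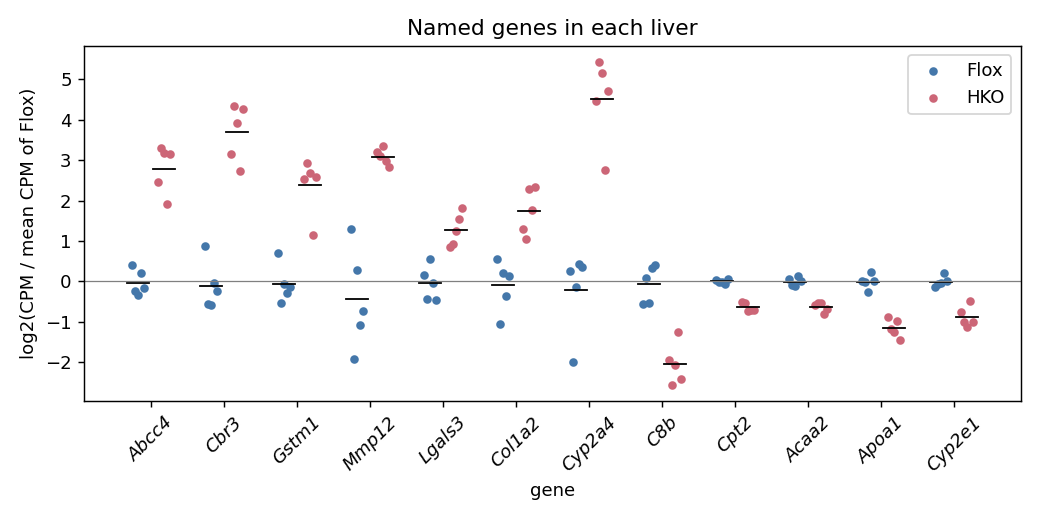
Log2 of the CPM of 12 named genes in each of the 10 livers relative to the mean CPM of Flox, with points for single livers and lines for the mean of each group (n = 5). Abcc4, Cbr3, Gstm1, Mmp12, Lgals3, Col1a2 and Cyp2a4 lie above all Flox livers in all 5 HKO livers, and C8b, Cpt2, Acaa2, Apoa1 and Cyp2e1 below.

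Genes known to differ between male and female livers shifted away from the male side. Of 15 male-biased genes 6 were lower, 1 higher and 8 did not pass (adjusted over the list alone, 8 lower and 1 higher), with a median of -0.73 (camera adjusted p = 0.00334, adjusted p = 0.660 with an estimated correlation). C8b, a complement component, fell 3.91-fold, from 180 ± 54.1 to 46.0 ± 17.9 CPM (mean ± SD, n = 5 each; edgeR adjusted p = 0.00288), and the fatty acid elongase Elovl3 fell by 2.30 on the log2 scale (edgeR adjusted p = 0.00687), each in 5 of 5 HKO livers. Of 10 female-biased genes 3 were higher, 0 lower and 7 did not pass (adjusted over the list alone, 4 higher), with a median of 1.08 (camera adjusted p = 0.0356, adjusted p = 0.660 with an estimated correlation). They were Cyp2a4, Sult3a1 and the transcription factor Cux2, at log2 fold changes of 4.74, 3.97 and 0.94 (edgeR adjusted p = 0.00124, 0.0236 and 0.0207). The call of Cux2 was lost without HKO 4 and HKO 5 (edgeR adjusted p = 0.105) and in the 6 livers (edgeR adjusted p = 0.132). Transcripts of 4 Y chromosome genes summed to between 107 and 136 CPM in all 10 livers, while Xist was at 23.2 and 24.3 CPM in HKO 4 and HKO 5 and at most 3.18 CPM elsewhere. Without HKO 4 and HKO 5 the medians of the male-biased and female-biased lists were -1.09 and 1.69, the latter over 12 tested genes where all 10 livers had 10. Male-biased genes were then lower in 4, and in 3 in the 6 livers. With all 10 livers fry called neither list (fry adjusted p = 0.114 for each). Neither score per liver passed (exact permutation adjusted p = 0.0813 for male-biased and 0.115 for female-biased genes). Flox 1 and Flox 3 had male-biased scores of 6.58 and 6.41, within the HKO range of 5.88 to 6.73. The female-biased score of HKO 4, 2.78, lay below those of Flox 1, Flox 3 and Flox 4 (3.77, 3.65 and 2.88).

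Targets of NRF2, the regulator of antioxidant and conjugating enzymes, were higher. Of 23 genes 10 rose, 1 fell and 12 did not pass (adjusted over the list alone, 12 rose and 1 fell), with a median of 0.53 (camera adjusted p = 0.00107, adjusted p = 0.71 with an estimated correlation). Without HKO 4 and HKO 5, 11 rose and 0 fell. The efflux transporter Abcc4 rose 7.36-fold, from 3.11 ± 0.703 to 22.9 ± 8.08 CPM, and the carbonyl reductase Cbr3 14-fold, from 0.865 ± 0.420 to 12.1 ± 5.29 CPM (mean ± SD, n = 5 each; edgeR adjusted p = 4.4e-04 and 5.1e-04). The glutathione transferase Gstm1 rose 5.59-fold and Gsta1 14.5-fold (edgeR adjusted p = 0.00190 and 0.00231), though reads of these families could be split between near-identical copies. All 5 HKO livers lay above all Flox livers in these 4 genes. The score of the whole list overlapped, with HKO 4 at 6.56 and Flox 1 at 6.67 (exact permutation adjusted p = 0.0651).

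Extracellular matrix genes were higher in HKO livers. Of 27 genes 16 rose, 0 fell and 11 did not pass (adjusted over the list alone, 25 rose), with a median of 0.98 (camera adjusted p = 7.2e-11, adjusted p = 0.390 with an estimated correlation). The collagen genes Col1a2 and Col5a2 had log2 fold changes of 1.84 and 1.57, and the matrix-degrading enzymes Mmp12 and Mmp13 of 3.09 and 2.64 (edgeR adjusted p = 0.00765, 0.00737, 0.00511 and 0.00633), with all 5 HKO livers above all Flox livers. Mmp12 went from 1.81 ± 1.59 to 15.5 ± 2.09 CPM (mean ± SD, n = 5 each). Without HKO 4 and HKO 5, which carried the epidermal and muscle transcripts, 5 of the genes passed and the median was 0.93, and in the 6 livers 9 passed.

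Markers of recruited and lipid-associated macrophages and monocytes rose with them. Of 15 genes 10 rose, 0 fell and 5 did not pass (adjusted over the list alone, 11 rose), with a median of 1.11 (camera adjusted p = 2.5e-08, adjusted p = 0.161 with an estimated correlation). Without HKO 4 and HKO 5, 7 rose with a median of 0.93, and in the 6 livers 5 rose and 1 fell. Lgals3 (galectin), Cd63 and Spp1 (osteopontin) had log2 fold changes of 1.32, 0.97 and 0.89 (edgeR adjusted p = 0.00589, 0.00604 and 0.00675, 5 of 5 HKO livers above every Flox liver). Resident Kupffer cell markers did not pass (camera adjusted p = 0.341, median 0.24, 0 of 12 higher and 2 lower, also adjusted over the list alone), and the lower ones were C6, which the male-biased list also holds, and Nr1h3, at -1.64 and -0.23 (edgeR adjusted p = 0.0115 and 0.0454, 5 of 5 HKO livers below every Flox liver).

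Lists of several other cell types also passed with higher markers. Sinusoidal endothelial cells had 2 of 13 genes higher and 0 lower (adjusted over the list alone, 6 higher), with a median of 0.26 (camera adjusted p = 0.0140, adjusted p = 0.71 with an estimated correlation), among them Mrc1 at 0.56 (edgeR adjusted p = 0.00867). Stellate cells and fibroblasts had 2 of 13 genes higher and 0 lower (adjusted over the list alone, 4 higher), with a median of 0.38 (camera adjusted p = 0.0229, adjusted p = 0.71 with an estimated correlation). These were Lrat, which makes retinyl esters, and the growth factor receptor Pdgfrb, at 0.67 and 0.82 (edgeR adjusted p = 0.00911 and 0.0395). Pdgfrb lost its call without HKO 4 and HKO 5 (edgeR adjusted p = 0.124, log2 fold change 0.85) and in the 6 livers (edgeR adjusted p = 0.156, log2 fold change 0.96). Cholangiocyte and progenitor-like markers had 3 of 11 genes higher and 0 lower (also adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.0259, adjusted p = 0.562 with an estimated correlation). They were Cd24a, Epcam and Cldn4 at 1.17, 1.08 and 2.90 (edgeR adjusted p = 0.0113, 0.0247 and 0.0279), and 0 of the 11 passed without HKO 4 and HKO 5. In Mrc1, Lrat, Pdgfrb, Epcam and Cldn4 all 5 HKO livers lay above all Flox livers. Neutrophil markers passed as a list with a median of 1.07 (camera adjusted p = 0.0409, adjusted p = 0.660 with an estimated correlation), though 0 of 7 genes passed singly, also adjusted over the list alone. Skeletal muscle markers had a median of 3.45, with 2 of 5 higher (adjusted over the list alone, 5 higher; camera adjusted p = 0.0259, adjusted p = 0.660 with an estimated correlation). That call was lost without HKO 4 and HKO 5 (camera adjusted p = 0.192), which held 291 and 319 CPM of skeletal muscle transcripts against at most 7.52 CPM elsewhere.

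Markers of T and NK cells did not pass (camera adjusted p = 0.167, median -0.37), with 0 of 11 higher and 1 lower (adjusted over the list alone, 2 lower). That gene was Cd4, at -1.53 (edgeR adjusted p = 0.0176, 5 of 5 HKO livers below every Flox liver). B and plasma cell markers (0 of 10, median 0.06, camera adjusted p = 0.517), red blood cell markers (1 of 8 lower, median 0.18, adjusted p = 0.895) and mesothelial markers (0 of 5, median -0.08, adjusted p = 0.792) did not pass either, with the same numbers adjusted over the list alone. The red blood cell gene was Alas2 of heme synthesis, at -0.78 (edgeR adjusted p = 0.00223, lower in 5 of 5 HKO livers).

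**Figure D3:**
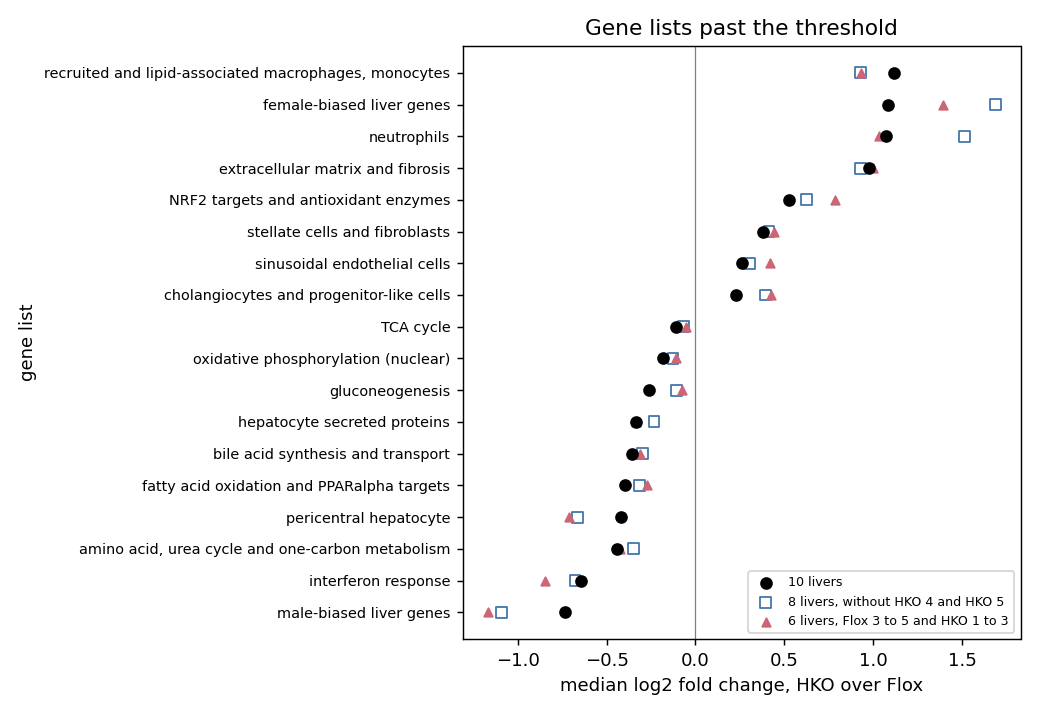
Median log2 fold change (HKO over Flox) of each gene list past the camera threshold, with all 10 livers (circles), with 8 livers without HKO 4 and HKO 5 (squares) and with the 6 livers Flox 3 to 5 and HKO 1 to 3 (triangles). The skeletal muscle list, at 3.45, is left out of the drawing. With all 10 livers the other medians run from -0.73 for male-biased genes to 1.11 for recruited macrophages. The tested members of the female-biased and neutrophil lists differ between the fits, 10 and 7 with all livers and 12 and 9 with 8 or 6 livers.

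Interferon response genes were lower in 6 of 24, higher in 0 and did not pass in 18 (adjusted over the list alone, 8 lower), with a median of -0.64 (camera adjusted p = 2.4e-05, adjusted p = 0.660 with an estimated correlation). Irf9, Rsad2 and Ifit3 fell by 0.67, 0.75 and 0.88 on the log2 scale (edgeR adjusted p = 0.0159, 0.0262 and 0.0347), with some overlap between the groups. Flox 3 had a mean log2 CPM of 5.55 over the list, and the other Flox livers 4.52 to 4.77. Only 2 of the 24 genes fell without HKO 4 and HKO 5, where Rsad2 and Ifit3 lost their calls (edgeR adjusted p = 0.155 and 0.0898), and 4 fell in the 6 livers. Inflammatory cytokines and chemokines had 3 of 22 genes higher and 0 lower (adjusted over the list alone, 3 higher and 1 lower) and did not pass as a list (camera adjusted p = 0.171, median 0.24). The higher genes were the chemokine Ccl2, its receptor Ccr2, and Cxcl14, at 1.27, 1.46 and 0.90 (edgeR adjusted p = 0.0302, 0.0114 and 0.0465), with Ccr2 and Cxcl14 higher in 5 of 5 HKO livers than in any Flox liver. None of these 3 passed without HKO 4 and HKO 5 (edgeR adjusted p = 0.103, 0.0671 and 0.284), where their log2 fold changes were 1.25, 1.26 and 0.48. Acute phase proteins had 6 of 22 lower, 0 higher and 16 that did not pass (adjusted over the list alone, 7 lower), with a median of -0.14, a mean of 0.01 and camera adjusted p = 0.181. Itih3 and Itih4 fell by 0.81 and 0.54 on the log2 scale (edgeR adjusted p = 5.3e-04 and 0.00683, 5 of 5 HKO livers below every Flox liver). The fibrinogen gene Fgb had a log2 fold change of -0.46 (edgeR adjusted p = 0.00756, 5 of 5 HKO livers below every Flox liver), which was 0.044 after quantile normalization. MHC class II genes had 0 of 8 past the threshold, also adjusted over the list alone (median 0.30, camera adjusted p = 0.102).

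The lists of NADPH supply, fatty acid and triglyceride synthesis, lipid droplets and fatty acid uptake, glycolysis and glycogen, and cholesterol synthesis did not pass in all 10 livers, though single genes did. NADPH supply other than Me1 had 2 of 20 genes higher, 3 lower and 15 that did not pass (adjusted over the list alone, 2 higher and 4 lower), with a median of 0.26 and camera adjusted p = 0.597. The pentose phosphate enzymes Pgd and Tkt rose by 0.79 and 0.84 on the log2 scale (edgeR adjusted p = 0.00509 and 0.00700), and cytosolic isocitrate dehydrogenase Idh1 and the mitochondrial NAD kinase Nadk2 fell by 0.34 and 0.28 (edgeR adjusted p = 0.00632 and 0.0151, both lower in 5 of 5 HKO livers). Without HKO 4 and HKO 5, 3 NADPH supply genes rose and 1 fell (camera adjusted p = 0.277, fry adjusted p = 0.0165, adjusted p = 0.528 with an estimated correlation). In the 6 livers 4 of them rose and 1 fell (camera adjusted p = 0.262, fry adjusted p = 0.0328, adjusted p = 0.486 with an estimated correlation). Fatty acid and triglyceride synthesis had 3 of 22 genes higher, 1 lower and 18 that did not pass (adjusted over the list alone, 7 higher and 1 lower), with a median of 0.21 (camera adjusted p = 0.0725, and 0.00145 without HKO 4 and HKO 5, where adjusted p = 0.364 with an estimated correlation and 0.0165 by fry). In the 6 livers 6 rose and 0 fell (camera adjusted p = 5.2e-04, fry adjusted p = 0.00883, adjusted p = 0.30 with an estimated correlation). Elovl6, Acaca and Acss2 rose by 1.56, 1.09 and 0.32 on the log2 scale and Agpat2 fell by 0.38 (edgeR adjusted p = 0.00405, 0.0192, 0.0498 and 0.0157). Lipid droplet and fatty acid uptake genes split, with 4 of 21 higher and 4 lower (adjusted over the list alone, 5 higher and 4 lower), a median of 0.18 and camera adjusted p = 0.693. In the 6 livers this list passed as higher, with a median of 0.39 and 5 genes higher and 3 lower (camera adjusted p = 0.00597, fry adjusted p = 0.0273, adjusted p = 0.329 with an estimated correlation). Pparg rose by 0.80, while Fabp1, Fabp2 and Slc27a2 fell by 0.87, 0.69 and 0.61 (edgeR adjusted p = 0.00869, 0.0010, 5.3e-04 and 0.00179). Glycolysis and glycogen had 2 of 20 genes higher and 1 lower (adjusted over the list alone, 2 higher and 3 lower), with a median of -0.04 and camera adjusted p = 0.813. Pyruvate kinase Pklr and Gpi1 rose by 1.13 and 0.53, and Ldha fell by 0.68 (edgeR adjusted p = 0.00395, 0.00656 and 8.0e-04). Cholesterol synthesis had 1 of 24 genes higher and 2 lower (adjusted over the list alone, 2 higher and 3 lower), with a median of -0.07 and camera adjusted p = 0.319. Ebp and Srebf2 fell by 0.56 and 0.31 (edgeR adjusted p = 0.00302 and 0.0377). All 5 HKO livers lay beyond all Flox livers in Elovl6, Pparg, Fabp1, Fabp2, Slc27a2, Pklr, Gpi1, Ldha and Ebp, and not in Pgd, Tkt, Acaca, Acss2, Agpat2 and Srebf2.

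Of the remaining lists none passed in all 10 livers. Ferroptosis genes had 4 of 16 higher and 1 lower, also adjusted over the list alone (median 0.28, camera adjusted p = 0.102, and 0.0105 without HKO 4 and HKO 5, where adjusted p = 0.528 with an estimated correlation and 0.0783 by fry). In the 6 livers 6 rose and 0 fell (camera adjusted p = 0.00798, fry adjusted p = 0.00623, adjusted p = 0.329 with an estimated correlation). The ferritin genes Fth1 and Ftl1 and the peroxidase Gpx4 rose by 0.76, 0.60 and 0.69 and Steap3 fell by 0.43 on the log2 scale (edgeR adjusted p = 0.00985, 0.0114, 0.0189 and 0.0310). Unfolded protein and integrated stress response genes had 2 of 19 higher and 1 lower, also adjusted over the list alone (median -0.36, camera adjusted p = 0.245), namely Trib3 and Sesn2 at 1.54 and 0.59 and Calr at -0.48 (edgeR adjusted p = 0.00780, 0.00759 and 0.0143). Xenobiotic metabolism had 2 of 19 higher and 6 lower, also adjusted over the list alone (median -0.01, camera adjusted p = 0.207). Cyp2a5 and the efflux pump Abcb1a rose by 1.82 and 1.17 and Ces2a and Cyp2c50 fell by 0.74 and 0.66 (edgeR adjusted p = 0.00922, 0.00440, 9.3e-04 and 0.00349). The cell cycle had 1 of 24 higher, and 0 adjusted over the list alone (median 0.30, camera adjusted p = 0.102), which was Mcm2 at 0.40 (edgeR adjusted p = 0.0314). The groups did not overlap in Steap3, Sesn2, Trib3, Calr, Cyp2a5, Abcb1a, Ces2a, Cyp2c50 and Mcm2, and did in Fth1, Ftl1 and Gpx4. No gene passed, also adjusted over the list alone, in the lists of mitochondrially encoded genes (0 of 10, median -0.08, camera adjusted p = 0.181), the circadian clock (0 of 19, median 0.02, adjusted p = 0.851), immediate early genes (0 of 12, median -0.67, adjusted p = 0.299) and heat shock genes (0 of 8, median -0.57, adjusted p = 0.117). In the 6 livers the immediate early genes, a sign of handling, passed as lower with a median of -0.70 (camera adjusted p = 0.0152, fry adjusted p = 0.262, adjusted p = 0.636 with an estimated correlation). Egr1 and Ier2 were called there (edgeR adjusted p = 0.00613 and 0.0157).

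Other list members named above also lost their calls in the smaller fits while keeping their direction. Nadk2, Agpat2, Srebf2, Steap3, Mcm2 and Nr1h3 did so without HKO 4 and HKO 5 (edgeR adjusted p = 0.0923, 0.0873, 0.144, 0.165, 0.0827 and 0.221). Acadvl, Ebp, Pparg, Trib3, Itih4, Fgb, Col1a2, Abcb1a, Cyp2a5, C6 and Lgals3 did so only in the 6 livers (edgeR adjusted p from 0.0550 to 0.122). Srebf2 had a log2 fold change of -0.31 without HKO 4 and HKO 5 and was called in the 6 livers, at -0.38 (edgeR adjusted p = 0.0199).

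By size of change, the 12 genes furthest up in HKO included 5 whose calls were lost without HKO 4 and HKO 5 and in the 6 livers: Atp2a1 and Acta1 of skeletal muscle, Pof1b, Pkp1 and Clca3a2. Atp2a1 stood at 51.6 and 53.5 CPM in HKO 4 and HKO 5 and at or below 0.238 CPM in every other liver. Ivl, a protein of the epidermal envelope, had 16 to 154 counts in HKO livers and 0 to 8 in Flox livers (edgeR adjusted p = 0.0123). Its log2 fold change was 3.98 without HKO 4 and HKO 5 (edgeR adjusted p = 0.0845) and 7.84 in the 6 livers (edgeR adjusted p = 0.0290). The other 6 passed in both smaller fits. H19, an imprinted noncoding RNA, rose 30.6-fold, from 0.411 ± 0.299 to 12.6 ± 5.81 CPM, and Cyp2a4 26.7-fold, from 8.60 ± 3.89 to 229 ± 119 CPM (mean ± SD, n = 5 each; edgeR adjusted p = 0.00150 and 0.00124). Cyp2a4 and Cyp2a5 are close copies whose reads could be split. Sprr1a, Gsta1, A4gnt and Sult3a1 rose by 4.74, 3.86, 3.98 and 3.97 on the log2 scale (edgeR adjusted p = 8.0e-04, 0.00231, 0.00897 and 0.0236). All 5 HKO livers lay above all Flox livers in H19, Cyp2a4, Sprr1a, Gsta1 and A4gnt, and not in Sult3a1.

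Me1 was among the 12 genes furthest down. Slco1a1, an organic anion uptake transporter, fell 13.9-fold, from 220 ± 123 to 15.8 ± 17.2 CPM, and Slc22a7, another organic anion transporter, 6.26-fold, from 29.2 ± 6.54 to 4.67 ± 0.749 CPM (mean ± SD, n = 5 each; edgeR adjusted p = 0.0126 and 3.0e-05). Igfbp2, which binds insulin-like growth factors, fell 6.44-fold, and Enho, which encodes the peptide adropin, 5.08-fold (edgeR adjusted p = 0.00238 and 4.6e-04). Serpina1e, Obp2a and Elovl3 had log2 fold changes of -2.86, -3.09 and -2.30 (edgeR adjusted p = 0.00613, 0.0363 and 0.00687). In these 7 genes all 5 HKO livers lay below all Flox livers. Only Elovl3 missed the threshold without HKO 4 and HKO 5 (edgeR adjusted p = 0.0611), and in the 6 livers Elovl3 and Obp2a did (edgeR adjusted p = 0.178 and 0.0603). Hsd3b5, Mup7 and Mup8 had log2 fold changes of -4.83, -2.61 and -2.56 (edgeR adjusted p = 0.0347, 0.0407 and 0.0274) and overlapped between the groups. Their calls were lost without HKO 4 and HKO 5 (edgeR adjusted p = 0.180, 0.0899 and 0.117), at log2 fold changes of -4.46, -2.99 and -2.73. Hsd3b5 stood at 1.40 and 1.99 CPM in Flox 1 and Flox 3, at 34.5 to 155 CPM in the other Flox livers and at 0.487 to 3.22 CPM in HKO. Flox 1 and Flox 3 were also the lowest Flox livers for Mup7 and Mup8. The major urinary protein genes have near-identical copies. Commd1b had 417 to 872 counts in Flox livers and 5 counts in all HKO livers together. It overlaps Commd1 and B3gnt2 on the same strand, so its reads cannot be assigned with certainty: Commd1b and B3gnt2 together had 20.4 ± 1.85 CPM in Flox and 17.8 ± 2.14 CPM in HKO (mean ± SD, n = 5 each; exact permutation p = 0.0794).

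**Figure D4:**
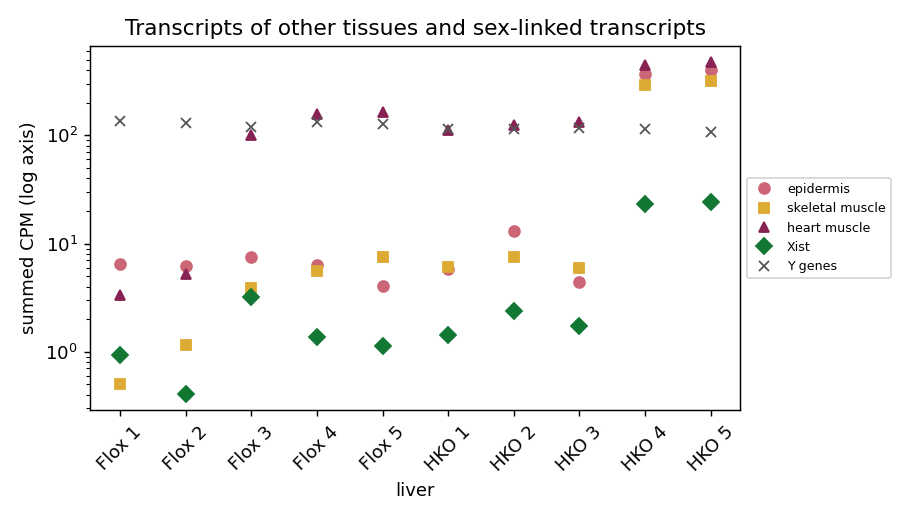
Summed CPM, on a log axis, of marker genes of epidermis, skeletal muscle, heart muscle, X inactivation (Xist) and the Y chromosome in each of the 10 livers. Epidermal markers are at 368 and 399 CPM in HKO 4 and HKO 5 and at or below 13 CPM in the other 8 livers.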

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

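All tests of explanations in this part, including the counts of other splits, were chosen only after the results they address had been seen.

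HKO 4 and HKO 5 held transcripts that a male liver has little of. Epidermal markers summed to 368 and 399 CPM there and to 4.08 to 13 CPM in the other 8 livers, skeletal muscle markers to 291 and 319 CPM against 0.498 to 7.52 CPM, and Xist was 7.29 times as high as in any other liver, while Y chromosome transcripts differed by at most 1.28-fold over all 10 livers. Tissue of the same male animals is argued against for the Xist part by that ratio of 7.29, and loss of Me1 by the epidermal sum of HKO 1 to HKO 3, which reached only 0.0353 of the lower of HKO 4 and HKO 5. RNA or reads of another sample in both libraries, a candidate source, stays open: over 22 epidermal and muscle genes the log2 ratio of HKO 5 to HKO 4 had an SD of 0.128, where all genes with as many counts had 0.387, so the transcripts stand in nearly the same proportions in both. Of the 65 tested genes at least 4-fold higher in these livers than in all others, 12 were among the 878 called higher.

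Extracellular matrix and macrophage genes were higher while hepatocyte genes were lower, which a smaller share of hepatocytes in the RNA could give. Markers of macrophages and of T and NK cells moved apart: the difference of their scores was 1.47 larger in HKO (SD 0.538 in Flox and 0.306 in HKO, exact permutation p = 0.00794). This cannot decide on that share, since the macrophage score alone separated the groups. T and NK markers also had low values (mean log2 CPM -1.02 in Flox and -1.32 in HKO). Sinusoidal endothelial, stellate, cholangiocyte and neutrophil scores differed by 0.30, 0.39, 0.63 and 1.04, and the mesothelial score by -0.15 (exact permutation adjusted p from 0.0813 to 0.765). The transcripts carried by HKO 4 and HKO 5 are argued against by the median of the extracellular matrix list in the 8 other livers, 0.93, and trends with gene length and GC content by its value of 0.97 relative to all genes with the trends removed. A smaller share of hepatocytes stays open. So do a larger number of macrophages and matrix-producing cells, higher expression within them, and a response to loss of Me1 in hepatocytes. Bulk RNA does not separate these.

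Male-biased genes were lower and female-biased genes higher in HKO. Female livers among the HKO libraries are argued against by the Y chromosome transcripts, whose lowest HKO sum was 0.895 of the lowest Flox sum. The transcripts carried by HKO 4 and HKO 5, Xist among them, are argued against by the median of the male-biased list in the other 8 livers, -1.09. A response to the genotype stays open as a hypothesis, as does chance variation between mice. The male-biased list lost its call with an estimated correlation and was not called by fry (fry adjusted p = 0.114).

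Among 100 splits of the 10 livers into groups of 5 drawn from the 126 possible, the real split alone gave as many genes: 1 of 100 for the total of 2034 (highest other 5), for the 878 higher (highest other 3) and for the 1156 lower (highest other 3). Chance is therefore argued against for these counts, 1 of 100 being the smallest share that these splits can give. For the 19 lists by camera chance cannot be excluded, since 18 of 100 splits gave at least as many and 1 split, Flox 2, Flox 3 and HKO 3 to HKO 5 against the rest, gave 25. For the 8 lists by fry the real split was again 1 of 100 (highest other 2), which argues against chance to the same degree.

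In 24 of 324 groups of 5 livers a single liver stood apart from the rest, by a gap to its neighbour above 0.71 of the group's range, where chance gives about 5% of groups. The values are that gap as a share of the range. Flox 1 was highest for Acss2 (0.804), Gpx4 (0.774), Me1 (0.726), Tkt (0.782), Ivl (1, the other Flox livers having 0 counts) and sinusoidal endothelial markers (0.734), and lowest for Srebf2 (0.821). Flox 2 was lowest for Cyp2a4 (0.759) and Sult3a1 (0.772) and highest for B and plasma cell markers (0.758). Flox 3 was highest for Pigr (0.802), the interferon response (0.760) and Clca3a2 (1, the other Flox livers having 0 counts), and Flox 5 was lowest for Pkp1 (0.757). HKO 1 was highest for Cbs (0.711) and mitochondrially encoded genes (0.806) and lowest for Cd24a (0.757). HKO 2 alone had counts of Commd1b (1), HKO 3 was highest for Trib3 (0.736), and HKO 5 was lowest for Hsd3b5 (0.761). HKO 4 was highest for Serpina1e (0.917) and lowest for Gpx4 (0.733), Gstm1 (0.780) and the ferroptosis list (0.766).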

How the results depend on the processing

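The alternatives that were chosen only after the data had been seen are the fits of 8 and of 6 livers, limma on log2(FPKM + 0.5), the fit without genes at least 4-fold higher in HKO 4 and HKO 5, and the fit with length and GC trends removed. So were the choices to judge a list by its median relative to all genes and to follow single genes only where they passed the threshold. The Me1 log2 fold change stayed between -3.00 and -2.50 with its call in all 27 alternatives that refit the genes. No paired analysis was possible because the title numbers are not shared between the groups and the labels pair no mice. Over the alternatives, calls of the named genes kept their direction and threshold in 2635 of 3104 comparisons, lost the threshold in 468 and turned in 1, the Fgb log2 fold change, at 0.044 after quantile normalization. Calls of lists were kept in 437 of 499 comparisons, lost in 60 and turned in 2, while lists without a call gained one in 37 of 574 and turned in 64. Amino acid metabolism, recruited macrophages, extracellular matrix, fatty acid oxidation, interferon response and NRF2 targets were called by camera in the same direction in all 27 refits. With an estimated correlation none of these 6 lists passed (adjusted p = 0.161 to 0.71). Fry did not call interferon response and NRF2 targets (fry adjusted p = 0.152 and 0.0605). Of the 24 genes named for their size, Me1, Cyp2a4, Gsta1, Igfbp2, Serpina1e, Slc22a7, Slco1a1 and Sprr1a kept their calls in all 27, and Pkp1 (8 of 20), Acta1 (9 of 26), Hsd3b5 (9 of 27) and Atp2a1 (9 of 25) kept them least often.

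Limma on FPKM without scaling between libraries put the median of all genes at 0.17, 0.13 and 0.15 (pseudocounts 0.1, 1 and 0.5) and gave 2653, 2637 and 2644 higher genes against 391, 390 and 389 lower, with 87.2%, 87.1% and 87.2% of calls higher, and 14 of the 24 named genes kept in each. These fits tested 10765 genes. Here and below, a named gene that a fit did not test counts as not kept. TMM scaling of the same FPKM values gave 894 higher and 924 lower, so the excess of higher genes comes with the missing scaling, and 14 named genes were kept. Fewer genes were tested at a mean FPKM of at least 5 (630 lower, 13 named genes kept), and 14 were kept without a filter. Quantile normalization gave 756 lower genes and kept 12. DESeq2 gave 1566 higher genes, with no adjusted p for 711 genes, and the first residual component as a covariate gave 1356. That component came from the residuals of the genotype fit. It is therefore uncorrelated with genotype and cannot adjust for a factor that separates the groups. The 8 livers gave 454 higher and 539 lower and the 6 livers 545 and 493, each with 14 named genes kept. Both fits had fewer livers and also lacked HKO 4 and HKO 5 with their transcripts of other tissues, and the counts do not separate these. Removing length and GC trends gave 753 lower genes and put the median of all genes at 0.083. Of the lists, 0 passed with an estimated correlation in camera and 8 by fry. Apart from the scaling of FPKM between libraries, the cause of these changes was not tested.

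Leaving out each liver in turn gave 498 to 1058 higher genes, 691 to 1162 lower genes, 15 to 20 lists and 14 to 19 of the named genes, and a log2 fold change of Me1 from -3.00 to -2.81. Higher genes fell to 537 without Flox 2, 511 without Flox 4, 540 without Flox 5 and 498 without HKO 5, and lower genes to 691 without HKO 5. Between 12 and 29 genes among those named lost their call without a single liver. Lists that lost their call were the TCA cycle (without Flox 1 or HKO 4), cholangiocytes (Flox 4 or HKO 2), sinusoidal endothelium (Flox 3), stellate cells (Flox 2 or HKO 3), skeletal muscle (Flox 1, HKO 4 or HKO 5), female-biased genes (HKO 1, HKO 2 or HKO 3), gluconeogenesis (Flox 1, HKO 3, HKO 4 or HKO 5) and neutrophils (Flox 1, Flox 2, Flox 3, HKO 1, HKO 2 or HKO 3).

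The medians that changed sign, relative to all genes, were these. Limma on FPKM put NADPH supply at -0.072, -0.047 and -0.059 (pseudocounts 0.1, 1 and 0.5), glycolysis at 0.033, 0.051 and 0.042, inflammatory cytokines at -0.14, -0.14 and -0.14, acute phase proteins at 0.081, 0.11 and 0.096, and periportal markers at 0.0045, 0.024 and 0.015. Pseudocounts 1 and 0.5 put cholesterol synthesis at 0.0093 and 0.0015 and the circadian clock at -0.0099 and -0.011, and pseudocount 1 put mitochondrially encoded genes at 0.0086. TMM scaling of FPKM put NADPH supply at -0.073, glycolysis at 0.031, inflammatory cytokines at -0.14, acute phase proteins at 0.077 and periportal markers at 0.0021. Quantile normalization put cholesterol synthesis at 0.028, glycolysis at 0.15, the TCA cycle at 0.053, inflammatory cytokines at -0.16, acute phase proteins at 0.23, the circadian clock at -0.043, periportal markers at 0.050, hepatocyte secreted proteins at 0.025 and mitochondrially encoded genes at 0.28. Without a filter the circadian clock was at -0.0089, and at a mean FPKM of at least 5 NADPH supply was at -0.071, glycolysis at 0.069 and mitochondrially encoded genes at 0.030. Voom with sample weights put glycolysis at 0.041, acute phase proteins at 0.083 and xenobiotic metabolism at 0.0063. The 8 livers put glycolysis at 0.13, the circadian clock at -0.023, periportal markers at 0.039 and mitochondrially encoded genes at 0.014. The 6 livers put glycolysis at 0.14, acute phase proteins at 0.11, periportal markers at 0.021 and mitochondrially encoded genes at 0.064. With length and GC trends removed xenobiotic metabolism was at 0.055 and mitochondrially encoded genes at 0.011. Leaving out single livers moved acute phase proteins from -0.28 to 0.014 (above 0 without Flox 1), the circadian clock from -0.067 to 0.10 (below 0 without Flox 2, Flox 4 or HKO 1), mesothelium from -0.31 to 0.051 (above 0 without Flox 3 or HKO 4), lipid droplet genes from -0.026 to 0.27 (below 0 without Flox 4), xenobiotic metabolism from -0.16 to 0.041 (above 0 without Flox 4, Flox 5 or HKO 4), B and plasma cells from -0.17 to 0.40 (below 0 without Flox 4 or HKO 3), glycolysis from -0.11 to 0.047 (above 0 without Flox 5 or HKO 4) and red blood cells from -0.14 to 0.40 (below 0 without HKO 2). For these changes of sign the cause was not tested.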

Other observations

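Genes of the proteasome, the complex that degrades ubiquitin-tagged proteins, were lower in HKO livers. The KEGG terms of the deposited table were tested only after the data had been seen, and 90 of 232 passed camera (56 higher, 34 lower), with 0 passing with an estimated correlation (lowest adjusted p = 0.336). Of 44 proteasome genes 29 fell and 0 rose, with a median log2 fold change of -0.33, and their mean log2 CPM went from 5.92 ± 0.0405 in Flox to 5.63 ± 0.0213 in HKO (mean ± SD, n = 5 each; exact permutation p = 0.00794). The proteasome had the smallest camera p of the 232 terms in these same livers. Its permutation p was not adjusted over the terms, so it adds no independent support. Relative to all genes the median was -0.34 with TMM, upper-quartile or DESeq2 scaling, -0.27 and -0.18 with TMM scaling and quantile normalization of FPKM, and -0.32 with length and GC trends removed, where 19 genes fell. In the 6 livers 18 fell. In limma on log2(FPKM + 0.5) without scaling 2 fell and 1 rose, at a median of -0.25 relative to all genes.

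Other KEGG terms lower in HKO were peroxisome (31 of 82 genes lower, 1 higher), breakdown of valine, leucine and isoleucine (25 of 49 lower, 0 higher) and spliceosome (23 of 128 lower, 0 higher), with camera adjusted p = 2.4e-10, 1.9e-12 and 1.9e-10 and adjusted p = 0.336 for each with an estimated correlation. Their medians stayed below all genes in each scaling tried. Without HKO 4 and HKO 5, 23, 15 and 7 genes of these terms fell, and in the 6 livers 15, 11 and 6. In limma on log2(FPKM + 0.5) without scaling 20, 14 and 2 fell and 6, 3 and 3 rose. With length and GC trends removed 30, 22 and 10 fell and 2, 1 and 0 rose. Ribosome genes (17 of 131 lower, 0 higher, camera adjusted p = 4.9e-08, adjusted p = 0.443 with an estimated correlation) and complement and coagulation genes (29 of 82 lower, 5 higher, camera adjusted p = 9.4e-05, adjusted p = 0.340 with an estimated correlation) had medians 0.061 and 0.0081 above all genes after quantile normalization. Lower genes numbered 3 and 24 without HKO 4 and HKO 5, 0 and 21 in the 6 livers, and 1 and 22 (with 8 and 9 higher) in limma on log2(FPKM + 0.5). With length and GC trends removed they numbered 6 and 27 (with 1 and 6 higher). ECM-receptor interaction had 16 of 71 genes higher and 3 lower (camera adjusted p = 7.4e-05, adjusted p = 0.341 with an estimated correlation), with 5 higher and 2 lower without HKO 4 and HKO 5 and 10 and 2 in the 6 livers.

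Heart muscle transcripts summed to 3.35 and 5.27 CPM in Flox 1 and Flox 2, to between 101 and 165 CPM in Flox 3 to Flox 5 and HKO 1 to HKO 3, and to 453 and 473 CPM in HKO 4 and HKO 5. In 8 livers with at least 100 counts of Myh6, the log2 values of 12 heart genes had an SD of 0.234 after removal of a single amount per liver. The origin of these transcripts was not tested.

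Counts followed gene length differently in the groups. The slope of log2 CPM per doubling of transcript length, relative to the mean of all livers, was between -0.058 and -0.015 in the Flox livers and between 0.0099 and 0.065 in the HKO livers (exact permutation p = 0.00794). The median log2 fold change was -0.16 in the shortest 10% and 0.0097 in the longest 10% of 8657 genes. Across genes, which are not independent replicates, Spearman's rho of fold change with length was 0.168 in all 10 livers, 0.115 in the 8 and 0.0714 in the 6.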
